A study of Schmidtea mediterranea with 11 samples.

How the data were processed

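Drop-seq libraries of adult Schmidtea mediterranea were sequenced for 11 samples in 9 groups, 2 groups of 2 libraries and 7 of 1 library. Per the labels' protocols, animals were kept at 20 °C, dissociated with trypsin and filtered, and whole cells were selected by Hoechst and calcein staining before droplet capture. Unfixed, DMSO-preserved and methanol-fixed cells were used, and X1 cells came from a sort that the other groups did not have. By the names of their files, 8 libraries came from 4 runs, and the 3 regeneration libraries carry no run name. Methanol replicate 1 was alone in its run. Unfixed replicate 1 shared a run with DMSO, unfixed replicate 2 with X1, and methanol replicate 2 with h2b(RNAi) and gfp(RNAi). The name of the day 4 file says day 3, and the label's day 4 was followed.

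The deposited tables hold whole-number counts, made by the authors as the number of unique molecular identifiers (UMIs) per transcript group and cell barcode. Per the submitters' processing notes, Picard 1.95, SAMtools 1.3 and STAR 2.5 were used. Their settings, the genome build and the rule by which barcodes were selected are not given in the sources used here. The tables were not normalised by the authors, as their whole-number values show.

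The tables of all libraries were joined by feature, which gave 28674 features and 37507 barcodes. Barcodes with at least 200 detected features were kept as cells, and 15720 were left out. Kept cells held 21623351 UMIs. Counts were scaled to 10000 per cell and logged in Scanpy 1.11.5, the 3000 most variable features were chosen by library, and 40 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 with seed 0 were used. Features seen in fewer than 3 cells were left out of clustering. Scrublet was run per library and called 34 of 21787 cells, which is too few to remove doublets, so none were removed in the values reported.

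A cluster was named for a cell type where at least 3 of its markers had at least 10 UMIs and at least 4-fold the level of all other cells, its 10 leading features did not contradict the name, and at least 25% of its cells carried a UMI of the markers. The 25% threshold was set after the clusters were seen. The 9 marker lists, for muscle, intestine, neural, epidermal lineage, parapharyngeal or parenchymal, cathepsin-positive, pharynx, protonephridia and neoblast cells, were recalled from published studies as feature IDs without gene names and were not checked against a source, and 50 of their 51 IDs were in the files. X1-rich clusters held at least 2 times the share of X1 cells than of unfixed replicate 2.

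Shares of cells have exact Clopper-Pearson 95% intervals, and ratios of shares have intervals from a normal approximation of the log ratio. Methanol and unfixed shares were compared by an exact two-sided permutation test. Methanol, X1 and unfixed libraries were compared on summed counts of kept cells in 1 fit of 5 libraries with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg threshold 0.05) in R 4.3.3. The fit had a biological coefficient of variation of 26.4%. The SE given for edgeR is the size of the log2 fold change over the square root of the test's F statistic. It is thus no measure of precision apart from the test. In simulated data with 200 features changed 4-fold, the edgeR test recovered 191 (95.5%) for methanol, with 23 false calls. For X1 it recovered 80 (40%), with 9 false calls. In both, false calls were a larger share of all calls than the threshold of 0.05. The Benjamini-Hochberg cut is looser with 200 true changes than with few, and recovery was not split by level of expression. The 95.5% is thus no measure of power where few features change or where features have few counts.

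Pairs of single libraries were compared without a test. A feature met the rule of size with at least 50 UMIs over both libraries and a 95% exact conditional binomial interval of the depth-scaled ratio wholly above 2 or below 0.5. On Poisson counts drawn for both libraries from the gfp(RNAi) profile, this recovered 194 of 200 features changed 4-fold, with 0 false calls. Only features with many UMIs were changed, and no spread between libraries or cells was simulated. The 0 thus says nothing about false calls in real pairs. A feature without a UMI in 1 library was set against a floor of 3 counts. X1-high and X1-low features met the same rule between X1 and unfixed replicate 2. Their median log2 ratios were taken over features with at least 10 UMIs in the pair, with 0.5 UMI put for a count of 0, and set against 10000 random lists matched in 20 bins of expression, with 1000 bootstrap draws. For features per cell, each cell was thinned to 500 UMIs and cells with fewer were left out.

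Named features were the 2 largest changes each way by ratio or log2 fold change among those that passed, a count of 0 in 1 library of a pair ranking first whatever its bound, with a mean of at least 50 CPM in the edgeR fit, and the markers listed. Groups, comparisons, marker lists, the rule for naming features and the settings above were chosen before the data were examined, except where a choice is said to have come later.

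Alternatives were DESeq2 1.42.0 (size factors and Wald test), no filter on low counts, all deposited barcodes, cells with at least 500 features, leaving out each replicate, a fit of all 11 libraries, Leiden resolution 0.5 and 2, 1500 variable features, removal of Scrublet calls, ComBat by library, thinning, other bounds for X1-rich clusters and X1 lists, TMM scaling and at least 200 UMIs. Chosen after the data were seen were clusters high in dd_Smed_v6_659_0, leaving out dd_Smed_v6_9705_0, barcodes with under 200 features, cells outside the X1-rich clusters and those high in dd_Smed_v6_659_0, leaving out the top 5% of cells by UMIs, and leaving out features held mostly by 1 cell.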

Results

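Planarians of the species Schmidtea mediterranea are freshwater flatworms that replace lost tissue from dividing stem cells, the neoblasts. Cells of adult animals were measured by Drop-seq, which captures single cells in droplets with barcoded beads and counts each transcript molecule by a unique molecular identifier (UMI). The 11 libraries fell into 9 groups. Wild-type cells were run unfixed (n = 2), preserved in DMSO (n = 1) or fixed in methanol (n = 2). X1 cells, a sorted fraction rich in neoblasts with replicated DNA, were run unfixed (n = 1). Double-stranded RNA against h2b, a histone gene that dividing cells need, or against gfp, a jellyfish gene used as the control, was injected 5 days before collection (n = 1 each), and regenerating animals were collected at day 0, day 2 and day 4 (n = 1 each); these 5 libraries were fixed in methanol. The gene targeted by the h2b injection could not be examined first, since the files do not pair feature IDs with gene names and its ID was not given. The labels do not say that replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

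The tables held 37507 barcodes, 28674 features and 25211447 UMIs, and 21787 cells with at least 200 detected features were kept. The unfixed replicates had 1301 and 843 kept cells with 1632661 and 572203 UMIs, and the methanol replicates had 3629 and 3819 cells with 4325485 and 4023013 UMIs. The DMSO library had 1371 cells and 1237969 UMIs, and X1 had 986 cells and 615436 UMIs. The h2b(RNAi) and gfp(RNAi) libraries had 1715 and 1628 cells with 1500800 and 1852384 UMIs. Day 0, day 2 and day 4 had 2498, 3203 and 794 cells with 2327358, 3031695 and 504347 UMIs. Barcodes left out numbered 570 and 2197 in the unfixed replicates, 505 and 362 in the methanol replicates, 959 in DMSO and 1511 in X1. They numbered 1065 in h2b(RNAi), 519 in gfp(RNAi), and 2204, 1793 and 4035 at day 0, day 2 and day 4. Shares of cells are over the kept cells only, and none was taken with a lower minimum. The median per kept cell ran from 519 UMIs at day 4 to 904 UMIs in unfixed replicate 1. All intervals given here are 95% intervals. They cover counting error only, except those of list medians, which come from bootstrap draws over the list's features, and the ranges of random lists.

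Clustering of the kept cells gave 25 clusters. Cluster 13 was muscle-like, cluster 18 neural-like, cluster 7 epidermal lineage-like, clusters 9 and 21 cathepsin-positive-like (a phagocytic and pigment cell group), and cluster 1 protonephridia-like (the excretory system). These 6 clusters held 32.7% of the kept cells. Their names, and each feature called a marker, rest on marker IDs recalled from published studies and not checked against a source. Cluster 11 passed the marker rule for intestine and cluster 19 that for parapharyngeal cells, but only 14.0% and 7.91% of their cells carried a UMI of those markers (1.01% and 1.49% of all other cells), and both were left unnamed by a 25% threshold set after the clusters were seen. The doublet caller did not work: it marked 0.156% of the cells, and no cell was removed as a doublet.

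The X1 library was compared with unfixed wild-type cells to see which transcripts go with the sorted neoblast fraction. Epidermal lineage markers and part of the muscle markers fell in X1 cells. Of 6 epidermal lineage markers tested, 5 fell (6 when adjusted over the list alone), among them dd_Smed_v6_61_0 by a log2 fold change of -5.11 ± 0.46 (SE) and dd_Smed_v6_332_0 by -4.25 ± 0.41. Of 6 muscle markers, 3 fell (5 adjusted over the list alone), led by dd_Smed_v6_323_0 at -5.70 ± 0.73. Of 5 neural markers 1 fell (3 adjusted over the list alone), dd_Smed_v6_6208_0 at -2.25 ± 0.44, and of 5 parapharyngeal or parenchymal markers dd_Smed_v6_210_0 fell, at -6.95 ± 0.61. Over that parapharyngeal list alone, 2 markers rose and 1 fell. None of 7 cathepsin-positive, 6 intestine, 3 pharynx, 5 protonephridia or 5 neoblast markers passed over all features. Adjusted over the list alone, 2 cathepsin-positive markers fell, 1 pharynx marker rose and 2 fell, no intestine or protonephridia marker passed, and 2 neoblast markers rose and 2 fell. The neoblast marker dd_Smed_v6_659_0 had a log2 fold change of 1.06 ± 0.30, with an adjusted p of 0.110 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all features.

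Over all 15420 features tested, edgeR called 301, of which 59 rose and 242 fell. Among features with a mean of at least 50 CPM (counts scaled by the library's total UMIs), the largest rises were those of dd_Smed_v6_2786_0 at a log2 fold change of 3.61 ± 0.53 and dd_Smed_v6_609_0 at 2.91 ± 0.55. Both rested on 1 cell, which held 94.3% of the 88 X1 UMIs of dd_Smed_v6_2786_0 and 90.8% of the 437 of dd_Smed_v6_609_0. With no UMI in X1, dd_Smed_v6_2223_0 was at least 237-fold lower and dd_Smed_v6_359_0 at least 60.6-fold lower than the mean of the unfixed libraries, against a floor of 3 counts in X1. For dd_Smed_v6_2223_0 that mean rested on unfixed replicate 1, at 2054 CPM against 259 in unfixed replicate 2 of X1's run, to which its ratio was at most 0.0188 and where 91.9% of its UMIs lay in 1 cell. In cells with at least 500 features the log2 fold change turned to -6.41 ± 6.73 for dd_Smed_v6_2786_0 and -0.88 ± 1.23 for dd_Smed_v6_609_0. There dd_Smed_v6_2223_0 and dd_Smed_v6_359_0, still without a UMI in X1, missed the threshold. Their SE, solved back from the test's F statistic, was 3.97 and 3.47, against 2.51 and 1.22. With all deposited barcodes dd_Smed_v6_2786_0 was at 2.35 ± 0.70 and dd_Smed_v6_609_0 at 1.65 ± 0.56 (edgeR adjusted p 0.121 and 0.159). Without unfixed replicate 1 they were at 3.58 ± 0.76 and 3.58 ± 0.65 (edgeR adjusted p 0.0875 and 0.0577). The 1 X1 library was assumed to vary like the replicate pairs, whose fit had 2 residual degrees of freedom. Without unfixed replicate 1 the count was 176, without unfixed replicate 2 it was 1492 and without methanol replicate 1 it was 185; it was 170 with no filter on low counts and 76 in cells with at least 500 features.

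**Figure D1:**
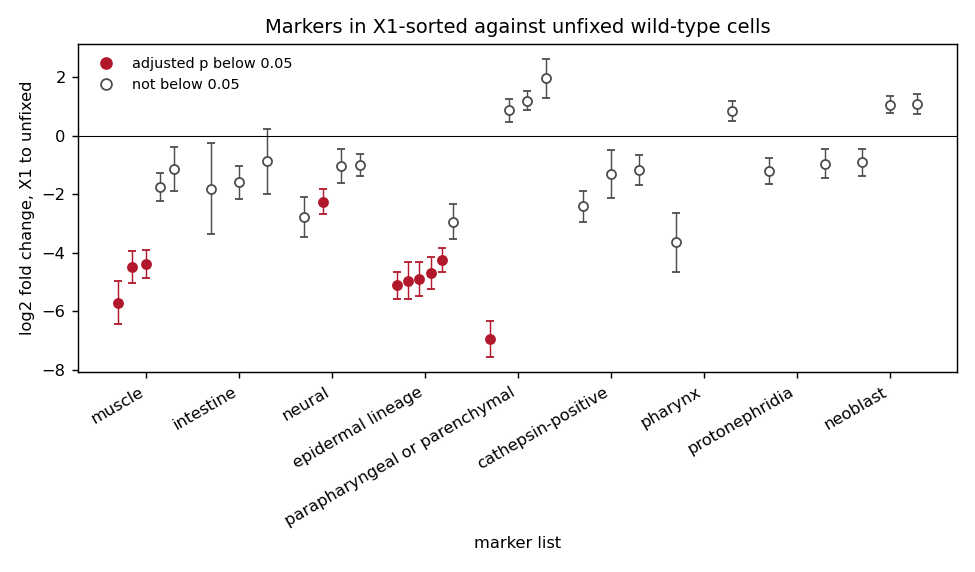
Log2 fold change of cell type markers in X1-sorted against unfixed wild-type cells (vertical axis) by marker list (horizontal axis). Each point is 1 marker with at least 50 UMIs over the 3 libraries and at least 1 in X1, with its standard error; filled points passed edgeR's test over all features, 10 of the 32 drawn, and those 10 lie below 0.

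Clusters holding at least 2 times the share of X1 cells than of the unfixed library of the same run were called X1-rich, which gave clusters 4 and 11. They held 76.7% of X1 cells (73.9 to 79.3, exact binomial) and 29.7% (26.6 to 32.9) of unfixed replicate 2. Their share was 14.7% in unfixed replicate 1, 13.4% and 16.2% in the methanol replicates and 24.7% in DMSO. Leading features of cluster 4 included dd_Smed_v6_9705_0 and dd_Smed_v6_7642_0, which also differed between libraries: dd_Smed_v6_9705_0 took 10.4% of kept UMIs in X1, 16.2% in unfixed replicate 2, 12.8% at day 4, 6.45% at day 0, 6.14% at day 2 and 0.635% to 1.71% in the other libraries, and dd_Smed_v6_7642_0 took 2.14% and 2.27% in unfixed replicate 1 and DMSO, which shared a run. A second set was therefore formed after the data were seen, the clusters 0, 3, 4, 10 and 11 in which dd_Smed_v6_659_0 was above its level over all kept cells. They held 90.4% of X1 cells and 39.6% of unfixed replicate 2.

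**Figure D2:**
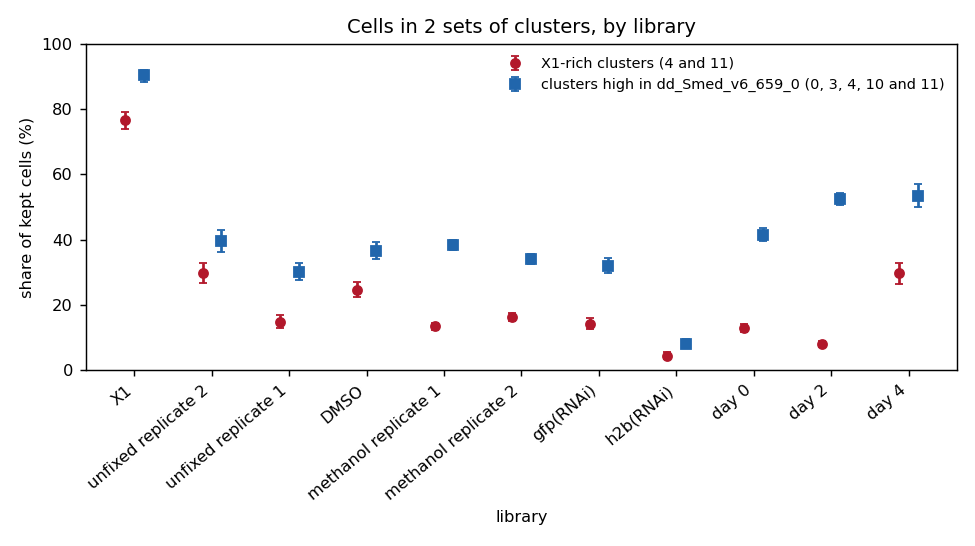
Share of kept cells (vertical axis, %) in X1-rich clusters (circles) and in clusters high in dd_Smed_v6_659_0 (squares) for each of the 11 libraries (horizontal axis), with exact binomial 95% intervals. X1 has the highest share of both sets, at 76.7% and 90.4%, and h2b(RNAi) the lowest, at 4.31% and 7.99%.

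Knockdown of h2b was compared with gfp(RNAi), 1 library each from the same run, to ask which cells and transcripts depend on dividing neoblasts. X1-rich clusters held 4.31% (3.40 to 5.39) of h2b(RNAi) cells and 14.1% (12.5 to 15.9) of gfp(RNAi) cells, a ratio of 0.305 (0.237 to 0.393); untreated methanol replicate 2 of that run had 16.2%. Clusters high in dd_Smed_v6_659_0 held 7.99% (6.75 to 9.37) against 31.9% (29.6 to 34.2). The neoblast marker dd_Smed_v6_659_0 itself had 237 UMIs in h2b(RNAi) and 1733 in gfp(RNAi), a depth-scaled ratio of 0.169 (0.147 to 0.193). With 1 library per group none of these differences has a replicate check. Correction of the expression values by library with ComBat turned the X1-rich ratio to 1.90. Since it works by library, that correction also takes out differences between conditions, here and in the comparisons below. Under it the X1-rich set was 1 cluster with 84.5% of X1 and 8.19% of unfixed replicate 2. ComBat thus cannot tell a library effect from that of a condition.

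Muscle-like, cathepsin-positive-like, protonephridia-like and neural-like cells made up more of the h2b(RNAi) library. Muscle-like cells were 14.9% (13.2 to 16.6) of h2b(RNAi) and 8.78% (7.45 to 10.3) of gfp(RNAi) cells, cathepsin-positive-like cells 10.6% (9.14 to 12.1) and 5.10% (4.08 to 6.28), and protonephridia-like cells 1.52% (0.993 to 2.21) and 0.491% (0.212 to 0.966). Neural-like cells were 14.0% (12.4 to 15.7) and 11.5% (9.98 to 13.1). Epidermal lineage-like cells were the exception, at 9.97% (8.59 to 11.5) against 12.9% (11.3 to 14.6). Without knockdown, methanol replicate 2 of the run had 7.86% neural-like cells, farther from gfp(RNAi) than h2b(RNAi) was, and 8.72% muscle-like, 5.81% cathepsin-positive-like, 0.367% protonephridia-like and 15.2% epidermal lineage-like cells. Methanol replicate 1 had 9.75%, 5.79%, 2.81%, 0.331% and 14.4% of these classes in turn. Among cells outside the X1-rich clusters and those high in dd_Smed_v6_659_0, the ratio of shares was 0.572 (0.475 to 0.690) for epidermal lineage-like, 0.902 (0.757 to 1.07) for neural-like, 1.25 (1.04 to 1.52) for muscle-like, 1.53 (1.20 to 2.0) for cathepsin-positive-like and 2.28 (1.04 to 5.03) for protonephridia-like cells. The unnamed clusters 11 and 19 held 1.34% and 4.26% of h2b(RNAi) cells and 1.72% and 3.81% of gfp(RNAi) cells. Unnamed clusters 2 and 17 had a listed muscle marker, dd_Smed_v6_2337_0, and a listed epidermal lineage marker, dd_Smed_v6_6573_0, among their leading features. They went against the named classes. Cluster 2 held 28 of 1715 h2b(RNAi) cells and 58 of 1628 gfp(RNAi) cells, and cluster 17 held 74 and 39. In cells with at least 500 features the ratio over all cells was 1.09 for the epidermal lineage-like and 0.971 for the muscle-like class, so both directions turned there.

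**Figure D3:**
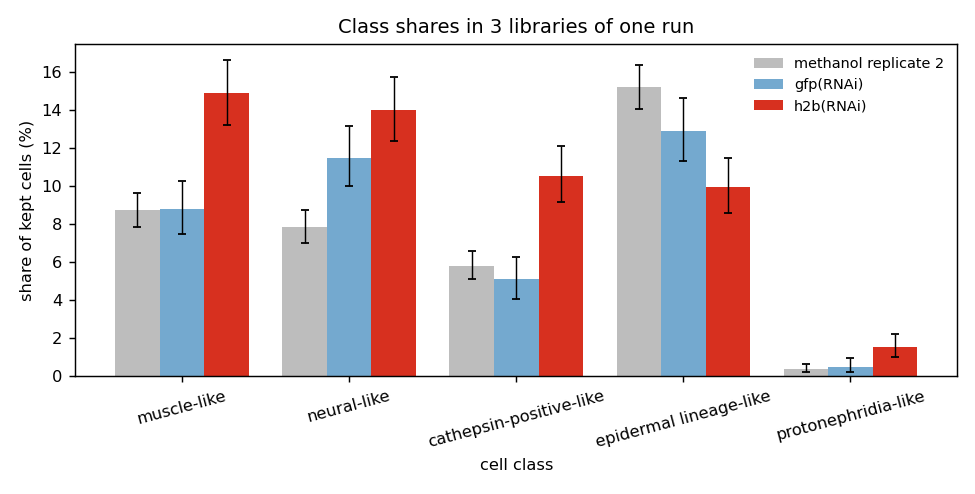
Share of kept cells (vertical axis, %) in 5 named cell classes (horizontal axis) for methanol replicate 2, gfp(RNAi) and h2b(RNAi), which shared a run; bars are 1 library each, with exact binomial 95% intervals. Muscle-like cells reach 14.9% and cathepsin-positive-like cells 10.6% in h2b(RNAi), while epidermal lineage-like cells are at 9.97%.

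Marker levels were compared by a rule of size, at least 50 UMIs over both libraries and an interval wholly above 2 or below 0.5. Of 7 cathepsin-positive markers measured, 3 met it upward, among them dd_Smed_v6_9_0 with a ratio of 4.15 (3.70 to 4.65). Of 6 muscle markers 2 did, including dd_Smed_v6_323_0 at 2.15 (2.02 to 2.29), whose interval was 1.87 to 2.13 under TMM scaling. Of 3 intestine, 4 parapharyngeal and 3 protonephridia markers 1 each met it upward, the parapharyngeal one being dd_Smed_v6_210_0 at 7.47 (6.64 to 8.42). Here gfp(RNAi) was the low library, since untreated methanol replicate 2 was at 6.41 (5.73 to 7.19) times its level. None of 6 epidermal lineage, 4 neural or 3 pharynx markers met it either way, and the median log2 ratios of these lists were 0.52, 0.87 and 0.24. The epidermal lineage median thus lay above 0, although the share of epidermal lineage-like cells was lower in h2b(RNAi). Of 5 neoblast markers, dd_Smed_v6_659_0 was lower and dd_Smed_v6_2089_0 higher, at 4.42 (2.29 to 9.21), and the list's median log2 ratio was 0.47.

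Features that separated X1 from the unfixed library of its run were then followed as lists, 73 X1-high and 202 X1-low features fixed without the RNAi libraries. The X1-high features had a median log2 ratio of -0.82 of h2b(RNAi) to gfp(RNAi), with 62 of 73 below 0, lower than each of 10000 random lists matched on expression (central 95% of lists -0.21 to 0.25). The X1-low features had a median of 0.96, with 185 of 201 above 0, higher than each of 10000 random lists (-0.21 to 0.08). The background between methanol replicate 2 and gfp(RNAi) was 0.32 and 0.01, at the 99.5 and 0 percentile of random lists, and between the methanol replicates it was -0.15 and -0.31, at the 30.4 and 0 percentile. A rank beyond the random lists was thus also met without h2b knockdown. In cells outside the X1-rich clusters and those high in dd_Smed_v6_659_0 the medians were -0.52 and 0.43, and the 6 X1-high features with a bound of at least 4-fold had a median of 0.54.

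By the rule of size, 328 features were higher and 146 lower in h2b(RNAi) of 8661 measured, or 262 and 189 under TMM scaling, which moved every log2 ratio by -0.11. The largest measured ratio was 103 (39.8 to 379) for dd_Smed_v6_254_0, with 43.8% of its UMIs in 1 cell. The feature dd_Smed_v6_465_0 had 66 UMIs in 7 h2b(RNAi) cells and none in gfp(RNAi), at least 27.2-fold higher against a floor of 3 counts, with 57.6% of its UMIs in 1 cell. The smallest ratios were 0.00823 (0.000207 to 0.0466) for dd_Smed_v6_12374_0 and 0.00891 (0.00107 to 0.0325) for dd_Smed_v6_10756_0, with 95.3% and 63.2% of their gfp(RNAi) UMIs in 1 cell. Outside the X1-rich clusters and those high in dd_Smed_v6_659_0 the counts were 111 and 23. For background, the 2 methanol replicates differed in 71 and 70 features by the same rule, and the 2 unfixed replicates in 264 and 68, both pairs from different runs. Within the run of h2b(RNAi), methanol replicate 2 without knockdown had 37 higher and 120 lower than gfp(RNAi).

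Regenerating animals were compared with day 0 to follow cell classes after wounding, with 1 library per day. Muscle-like cells, which are cluster 13 alone, were 9.05% (7.95 to 10.2) at day 0, 4.4% (3.72 to 5.17) at day 2 and 4.28% (2.98 to 5.93) at day 4. Cluster 2, unnamed, was led by the listed muscle marker dd_Smed_v6_2337_0 and went the other way. It held 104 of 2498 cells at day 0, 228 of 3203 at day 2 and 45 of 794 at day 4. The fall of cluster 13 is thus no measure of all muscle cells. Epidermal lineage-like cells were 14.5% (13.2 to 16.0), 10.5% (9.48 to 11.6) and 10.5% (8.41 to 12.8), and neural-like cells 5.72% (4.85 to 6.71), 7.65% (6.75 to 8.62) and 7.81% (6.04 to 9.90). Cathepsin-positive-like cells were 3.04% (2.40 to 3.79), 2.5% (1.98 to 3.10) and 1.51% (0.783 to 2.63), and protonephridia-like cells 0.200%, 0.0624% and 0.126%, on 5, 2 and 1 cells. Clusters 11 and 19, unnamed, held 1.16% and 3.40% at day 0, 0.656% and 3.84% at day 2, and 1.39% and 3.90% at day 4. With cells thinned to 500 UMIs and clustered again, which left out 768, 910 and 374 cells of day 0, day 2 and day 4 with fewer UMIs, the muscle-like ratio to day 0 was 1.13 at day 2 and 1.01 at day 4, and the neural-like ratio at day 4 was 0.848. In cells with at least 500 features the muscle-like ratio was 1.34 (0.941 to 1.91) at day 2 and 1.87 (0.976 to 3.59) at day 4, so its direction turned there too.

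**Figure D4:**
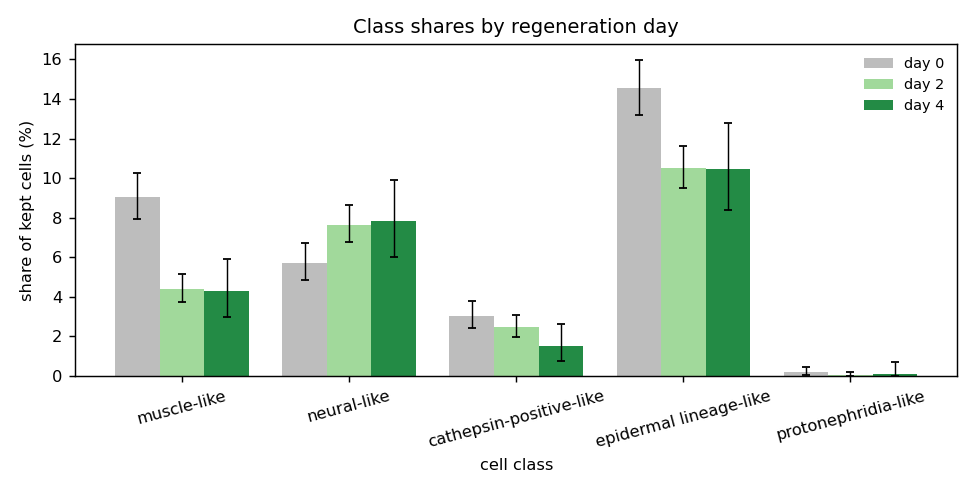
Share of kept cells (vertical axis, %) in 5 named cell classes (horizontal axis) at regeneration day 0, day 2 and day 4; bars are 1 library each, with exact binomial 95% intervals. The muscle-like share is 9.05% at day 0 and 4.28% at day 4, and the neural-like share 5.72% and 7.81%.

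X1-rich clusters held 12.8% (11.5 to 14.2) of cells at day 0, 7.96% (7.05 to 8.95) at day 2 and 29.6% (26.4 to 32.9) at day 4, and clusters high in dd_Smed_v6_659_0 held 41.5% (39.6 to 43.5), 52.5% (50.7 to 54.2) and 53.4% (49.9 to 56.9). The day 2 library thus lay below day 0 by the first measure and above it by the second, and 7 of the 11 alternatives tried for the first measure turned its direction. The level of dd_Smed_v6_659_0 was 1.27 (1.21 to 1.33) times that of day 0 at day 2 and 0.970 (0.888 to 1.06) times at day 4, while the 4 neoblast markers measured had a median log2 ratio of -0.10 and -0.76. X1-high features had median log2 ratios to day 0 of -0.04 at day 2 and -0.15 at day 4, at the 37.1 and 24.5 percentile of random lists. With the X1-high list made against the unfixed library of the other run the medians were 0.09 (0.00 to 0.16) and 0.37 (0.25 to 0.50). X1-low features had medians of -0.31 at day 2, with 156 of 199 below 0, and -0.30 at day 4, with 117 of 198 below 0, at the 0 and 0.1 percentile. Between the 2 methanol replicates the X1-low median was also -0.31, with 148 of 202 below 0, at the 0 percentile. The values of the 2 days thus did not go beyond a difference between libraries. For X1-rich clusters the day 4 to day 0 ratio of 2.31 was 0.790 in cells with at least 500 features, and 7 other alternatives moved it, to between 1.29 in clusters high in dd_Smed_v6_659_0 and 6.16 with ComBat. In cells with at least 500 features, 96 at day 4, the X1-rich set was another one. It held 29.9% of X1 and 3.76% of unfixed replicate 2 cells.

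By the rule of size, 35 features were higher and 57 lower at day 2 than at day 0, of 9302 measured. At day 4, 70 were higher and 113 lower of 6668 measured, or 46 and 219 under TMM scaling, which moved every day 4 log2 ratio by -0.26. Without dd_Smed_v6_9705_0 the day 4 counts were 88 and 84. Both day comparisons share the day 0 library, so their lists are not independent. For background, the 2 methanol replicates, from different runs and with more UMIs, differed in 71 and 70 of 12348 features by the same rule. The day 2 counts were not above these, so they cannot be told from a difference between libraries. The muscle marker dd_Smed_v6_702_0 was lower at day 2, with a ratio of 0.244 (0.213 to 0.280), while the muscle list's median log2 ratio was 0.01 at day 2 and 0.26 at day 4. The epidermal lineage marker dd_Smed_v6_332_0 was lower at day 4, at 0.292 (0.257 to 0.331). Of the marker lists, 1 of 4 muscle markers was lower and 1 of 5 parapharyngeal markers higher at day 2, and at day 4 the only intestine marker measured, 1 of 6 epidermal lineage and 1 of 5 parapharyngeal markers were lower and 1 of 5 parapharyngeal markers higher. At day 2 the largest ratios were 160 (28.5 to 6367) for dd_Smed_v6_7131_0, with 95.7% of its UMIs in 1 cell, and 112 (19.8 to 4457) for dd_Smed_v6_1936_0. The latter had 146 UMIs in 31 cells at day 2 and 1 UMI at day 0. The smallest ratios were 0.0405 (0.0279 to 0.0569) for dd_Smed_v6_2223_0 and 0.0461 (0.00919 to 0.143) for dd_Smed_v6_1792_0. At day 4 dd_Smed_v6_7131_0 had a ratio of 392 (68.5 to 15673), with 95.3% of its UMIs in 1 cell, and dd_Smed_v6_385_0 one of 51.8 (26.2 to 117), with 76.2% in 1 cell. The smallest measured ratios at day 4 were 0.00510 (0.00311 to 0.00787) for dd_Smed_v6_100_0 and 0.0152 (0.0120 to 0.0191) for dd_Smed_v6_6998_0, both singled out after their values were seen. With no UMI at day 4, dd_Smed_v6_873_0 and dd_Smed_v6_4963_0 had ratios to day 0 of at most 0.204 and 0.239 against the floor of 3 counts.

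Methanol fixation was compared with unfixed cells to see what preservation does to the profile. Few features separated the groups. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 8 of 15420 features passed, 2 up and 6 down in methanol. Those that rose were dd_Smed_v6_2169_0, at a log2 fold change of 4.89 ± 0.41 (adjusted p 0.00896, n = 2 and 2), and dd_Smed_v6_365_0, at 4.62 ± 0.37 (adjusted p 0.00896), for which 1 cell held 92.2% and 77.8% of the UMIs of the methanol replicates. Above the same 50 CPM, the largest falls were -5.44 ± 0.54 for dd_Smed_v6_85086_0 (adjusted p 0.0238) and -3.09 ± 0.34 for dd_Smed_v6_15410_0 (adjusted p 0.0307). Without methanol replicate 1, dd_Smed_v6_2169_0, dd_Smed_v6_365_0 and dd_Smed_v6_15410_0 missed the threshold with folds of like size, at 4.70 ± 0.53, 4.48 ± 0.50 and -3.37 ± 0.54, as did dd_Smed_v6_15410_0 without methanol replicate 2, at -2.93 ± 0.52; each of these fits had 1 residual degree of freedom. With all deposited barcodes dd_Smed_v6_2169_0 was at 2.76 ± 0.70 (edgeR adjusted p 0.275), and in cells with at least 500 features dd_Smed_v6_365_0 was at 1.74 ± 1.18 (edgeR adjusted p 0.709). No marker of the 9 lists passed over all features. Adjusted over the list alone, 1 intestine, 1 neural and 1 epidermal lineage marker fell, and 1 parapharyngeal and 2 cathepsin-positive markers rose, while no muscle, pharynx, protonephridia or neoblast marker passed. The parapharyngeal one, dd_Smed_v6_385_0, had 87.4% of its 669 UMIs of methanol replicate 1 in 1 cell, and 54 UMIs in methanol replicate 2. At an unadjusted p under 0.05 there were 1614 features, DESeq2 called 36, and without unfixed replicate 2 edgeR called 629, without unfixed replicate 1 it called 43, and without methanol replicate 1 or 2 it called 1 or 5. No run held both methods in wild-type cells. Of the 8 features, 1 lay on the methanol side in each of the 5 other methanol-fixed libraries.

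Cell classes differed between methanol and unfixed libraries by no more than an exact permutation test of 2 against 2 can tell, whose smallest p is 0.333. Muscle-like cells were 7.25% ± 2.07 (SD, n = 2) in methanol and 5.07% ± 1.63 in unfixed libraries (exact two-sided permutation p 0.667), neural-like cells 8.81% ± 1.34 and 8.21% ± 2.15 (exact p 0.667), epidermal lineage-like cells 14.8% ± 0.568 and 15.2% ± 1.21 (exact p 1), cathepsin-positive-like cells 4.31% ± 2.12 and 2.89% ± 0.940 (exact p 0.667) and protonephridia-like cells 0.349% ± 0.0254 and 0.485% ± 0.183 (exact p 0.667). X1-rich clusters held 14.8% ± 1.97 and 22.2% ± 10.6 (exact p 0.667). That difference of -7.38 points was 0.106 without unfixed replicate 2 and -14.9 without unfixed replicate 1, and 5 of 15 alternatives turned its direction. Clusters 11 and 19 held 0.956% ± 0.167 and 3.51% ± 0.260 in methanol against 1.56% ± 0.472 and 2.56% ± 0.575 in unfixed libraries (exact p 0.333 each). With each cell thinned to 500 UMIs, the median cell had 323.5 ± 13.4 features in methanol and 303 ± 28.3 in unfixed libraries (exact p 0.667). The difference of 20.5 was 0.5 without unfixed replicate 2 and 40.5 without unfixed replicate 1. Unthinned, the median cell had 439.5 ± 6.36 and 393.5 ± 128. Thinning left out 838 and 1003 cells of the methanol and 226 and 358 cells of the unfixed replicates.

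The DMSO library was compared with unfixed replicate 1 of the same run, 1 library each. More features were lower than higher: 213 against 27 of 7624 measured. Of the markers, 2 of 6 muscle, 1 of 6 epidermal lineage, 1 of 3 intestine, 1 of 3 parapharyngeal and 1 of 3 pharynx markers were lower, including dd_Smed_v6_6573_0 of the epidermal lineage list at 0.391 (0.328 to 0.466), and none of the 9 lists had a higher one. No neural, cathepsin-positive, protonephridia or neoblast marker met the rule. Without a UMI in the unfixed library, dd_Smed_v6_518_0 was at least 75.2-fold and dd_Smed_v6_12374_0 at least 40.4-fold higher in DMSO, the latter with 98.9% of its UMIs in 1 cell. Unfixed replicate 2 held dd_Smed_v6_518_0 at 136 CPM, with 92.3% of its UMIs in 1 cell, near the 138 of DMSO. The smallest ratios were 0.0302 (0.00615 to 0.0902) for dd_Smed_v6_1936_0 and 0.0370 (0.0205 to 0.0615) for dd_Smed_v6_808_0. The 131 UMIs of dd_Smed_v6_1936_0 in unfixed replicate 1 lay in 9 cells, 38.9% of them in 1 cell, so its ratio rests on few cells. X1-rich clusters held 24.7% (22.4 to 27.0) of DMSO and 14.7% (12.8 to 16.7) of unfixed cells. That ratio of 1.68 was moved by 7 of 11 alternatives, to between 1.0 with 1500 variable genes and 9.01 with ComBat, and clusters high in dd_Smed_v6_659_0 held 36.5% and 30.1%. Epidermal lineage-like cells were 17.5% (15.5 to 19.6) and 14.3% (12.4 to 16.3). Muscle-like cells were 6.86% and 6.23%, neural-like cells 7.22% and 6.69%, cathepsin-positive-like cells 2.41% and 2.23% and protonephridia-like cells 0.438% and 0.615%, each within the other's interval, and clusters 11 and 19 held 1.17% and 2.48% against 1.23% and 2.15%. X1-high and X1-low features had median log2 ratios of 0.44 and -0.21, at the 100 and 0 percentile of random lists. Like ranks were met without DMSO. The X1-high median was 0.32 between methanol replicate 2 and gfp(RNAi), at the 99.5 percentile, and the X1-low median -0.31 between the methanol replicates, at the 0 percentile. With each cell thinned to 500 UMIs, the median cell of DMSO had 328 features, little more than that of the unfixed library, and the quartiles were 302.5 and 349 against 292 and 344. Unthinned, the direction was the opposite, at 380 against 484. With each cell thinned to 1000 UMIs, which left out 1001 and 735 cells, the median cell had 578 features in DMSO and 562.5 in the unfixed library.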

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

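The comparisons of barcodes with under 200 features were chosen after the data were seen. These barcodes lay outside the measurement of kept cells, and their counts still differed between libraries in the X1 features. X1-high features took 1.72% (1.67 to 1.77) of the UMIs of such barcodes in X1 and 0.559% (0.537 to 0.581) in unfixed replicate 2 of the same run. In kept cells they took 3.03% and 0.941%. The list was made from the kept cells of these libraries, so the barcodes are not an independent sample of animals.

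X1-low features had a median log2 ratio of h2b(RNAi) to gfp(RNAi) of 0.87 in barcodes with under 200 features, against 0.96 in kept cells. X1-high features had a median of -0.05 in those barcodes, against -0.82 in kept cells. No biological explanation was tested for either value.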

How the results depend on the processing

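The settings without dd_Smed_v6_9705_0, clusters high in dd_Smed_v6_659_0, barcodes with under 200 features and cells outside both cluster sets were chosen after results were seen. A ratio or list median was counted as unchanged within the interval of its main value, and a count of features within 1.5 times. Methanol minus unfixed differences were judged by sign alone, and single features of the edgeR fit by sign and call, so a change in their size was not counted. Among the values that answer a comparison, 117 alternatives were counted as unchanged, 65 as moved and 17 as turned in direction. Among single features and other values these were 365, 40 and 25, and 13 ended a call; for these the rule that any change of sign of a tested value counts as a turn was set after the values were seen. Where a value changed, the cause was not tested; thinning and the 500 feature minimum both removed cells and led to new clusters. No paired analysis was possible because the labels pair no samples.

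The count between methanol and unfixed libraries, 8, was 36 with DESeq2's Wald test, 50 in cells with at least 500 features, 5 with all deposited barcodes and 1 to 629 when leaving out each replicate. The count for X1 was 170 without a filter on low counts, 76 in cells with at least 500 features and 176 to 1492 when leaving out each replicate. In cells with at least 500 features the X1 log2 fold change was -6.41 for dd_Smed_v6_2786_0 and -0.88 for dd_Smed_v6_609_0. For markers near 0 in methanol, dd_Smed_v6_659_0 was at -0.00021 with DESeq2 size factors, -0.00042 with the Wald test, -0.079 in cells with at least 500 features and -0.048 to 0.11 when leaving out each replicate, and dd_Smed_v6_332_0 at -0.0331, -0.0333, -0.12 and -0.16 to 0.084.

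X1-rich clusters kept a ratio below 1 for h2b(RNAi) to gfp(RNAi) except with ComBat (1.90), and it was 0.130 in cells with at least 500 features. There the X1-rich set held 29.9% of X1 and 3.76% of unfixed replicate 2 cells. Its values, here and below, thus describe another set of cells than the main clusters do. Values with ComBat by library cannot tell a library effect from that of a condition, since the correction takes out both. For day 2 to day 0 the ratio was 1.22 and 1.32 at Leiden resolution 0.5 and 2, 1.36 with 1500 variable genes, 0.511 with at least 500 features, 1.29 with Scrublet calls removed, 3.27 with ComBat, 0.343 with cells thinned to 500 UMIs, 0.958 without dd_Smed_v6_9705_0, 1.3 at 1.5 times the share and 1.26 in clusters high in dd_Smed_v6_659_0. For day 4 it was 1.55 and 1.58, 1.35, 0.790, 1.47 and 6.16 in the order of the first 6 of these, 1.56 at 1.5 times the share and 1.29 in clusters high in dd_Smed_v6_659_0. At 4 times the share no cluster was X1-rich, so that setting gave no value. The methanol minus unfixed difference was 0.324 points at resolution 2, 1.83 with 1500 variable genes, 9.28 with at least 500 features, 1.36 in clusters high in dd_Smed_v6_659_0 and -14.9 to 0.106 when leaving out each replicate.

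For h2b(RNAi) to gfp(RNAi), the epidermal lineage-like ratio was 0.976 at resolution 2 and 1.09 with at least 500 features. The muscle-like ratio was 1.36 at resolution 0.5, 1.39 with 1500 variable genes, 0.971 with at least 500 features, 1.33 thinned and 1.36 without dd_Smed_v6_9705_0. The neural-like ratio was 1.57 with at least 500 features, and the cathepsin-positive-like ratio 1.39 at resolution 0.5, 1.38 with at least 500 features, 1.33 with ComBat and 1.34 thinned. For the days, the muscle-like ratio with at least 500 features was 1.34 at day 2 and 1.87 at day 4, and thinned 1.13 and 1.01, and the thinned neural-like ratio at day 4 was 0.848. Leaving out each replicate, the methanol minus unfixed difference ran from -1.23 to 0.489 points for epidermal lineage-like, -0.922 to 2.12 for neural-like and -0.0832 to 2.92 for cathepsin-positive-like cells. It was 1.15 for epidermal lineage-like cells at resolution 2, and for neural-like cells -1.48 with 1500 variable genes and -1.76 with at least 500 features.

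The X1-high median for h2b(RNAi) was 0.54 with a bound of 4-fold, on 6 features, -0.39 with at least 500 features, -0.054 in barcodes with under 200 features and -0.52 in cells outside both cluster sets. The X1-low median was 0.82 and 1.06 with bounds of 1.5-fold and 4-fold, 0.86 with TMM, 1.14 with at least 500 features, 0.87 in barcodes with under 200 features and 0.43 in the other cells. For day 2 the X1-high median was -1.04 with the 4-fold bound. For day 4 it was 0.37 with the list from the other run, -0.40 with TMM, -0.48 with at least 500 features, -0.048 without dd_Smed_v6_9705_0 and 0.065 in barcodes with under 200 features.

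By the rule of size with at least 200 UMIs, which measures fewer features, 151 features were higher and 60 lower in h2b(RNAi), 10 and 85 in DMSO, 12 and 37 at day 2 and 28 and 74 at day 4. In the other cells h2b(RNAi) had 111 and 23, and day 2 had 37 lower. With at least 500 features per cell, day 2 had 15 and 36, and day 4 had 40 and 58. With TMM, day 4 had 46 and 219. TMM moved log2 ratios by -0.11 for DMSO and 0.06 for day 2. Features per cell kept the sign of the methanol minus unfixed difference in every alternative run, from 0.5 to 46. Depth limited most the day 4 library, where 374 of 794 cells had under 500 UMIs.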

Other observations

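The tests below were chosen after the result was seen, except that of the 111 other features lower at day 4. Beyond the named classes, unnamed clusters also differed between the regeneration libraries. Cluster 3 held 15.7% (14.3 to 17.2) of cells at day 0, 29.0% (27.4 to 30.6) at day 2 and 14.99% (12.6 to 17.7) at day 4, cluster 12 held 7.45%, 2.75% and 1.26%, and cluster 2 held 4.16%, 7.12% and 5.67%. The first leading feature of cluster 2 was the listed muscle marker dd_Smed_v6_2337_0. With 1 library per day these shares have no replicate.

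Of the 8 features called between methanol and unfixed libraries, dd_Smed_v6_2169_0 was higher in methanol in all 7 methanol-fixed libraries, the lowest of them at 5.30 times the highest other library. The feature dd_Smed_v6_2169_0 was singled out for this pattern, so the ratio is no separate evidence for methanol fixation, which stays open. In methanol-fixed libraries the share of its UMIs in 1 cell ran from 14.9% in h2b(RNAi) to 96.8% at day 4. At day 4 only 4 cells carried its 94 UMIs, so its level there rests on 1 cell. For the remaining 7 features, 0 had all 5 other methanol-fixed libraries on the methanol side, a count fixed by setting dd_Smed_v6_2169_0 apart. Of the 7, dd_Smed_v6_85086_0 was at 29.6 and 10.9 CPM in the methanol replicates. At day 0, day 2 and day 4 it was at 450, 357 and 617 CPM, which argues against fixation as its only cause. In h2b(RNAi) and gfp(RNAi) it was at 29.98 and 54.0 CPM, on the methanol side, and over the 7 features 1 to 4 of the 5 libraries lay on that side. A difference between runs stays open for these, since 0 of 4 runs held both methods, and the groups of animals themselves were not tested.

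The feature dd_Smed_v6_11867_0, chosen after its values were seen, was nearly absent in h2b(RNAi), with 2 UMIs against 85 in gfp(RNAi), a ratio of 0.0290 (0.00346 to 0.108). In clusters outside the X1-rich ones and those high in dd_Smed_v6_659_0 the upper bound of the ratio was 0.216. There dd_Smed_v6_659_0 itself had a ratio of 0.199 (0.150 to 0.261). A listed marker of the cells that fell was thus lower there too, so the bound decides nothing about fewer such cells as the cause. At the gfp(RNAi) level 68.9 UMIs of dd_Smed_v6_11867_0 would be expected at that depth, which argues against depth. The ratio of dd_Smed_v6_11867_0 ranked 1 of 8613 features not held mostly by 1 cell. That it may be the target of the injected RNA stays open, since its sequence and name were not given.

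At day 4, dd_Smed_v6_100_0 had 20 UMIs against 18114 at day 0 and dd_Smed_v6_6998_0 had 75 against 22720, chosen after their values were seen. Over 11 clusters at day 0 the ratio of the 2 features differed by 1.19 times at most, and the level of dd_Smed_v6_100_0 in barcodes with under 200 features was 2.19 times that in kept cells, which is consistent with free RNA at day 0. Cluster 15, with 24 cells at day 0, was not among these 11, and its ratio was 0.848 there. It was 1.68 in unfixed replicate 1, 1.47 in methanol replicate 1 and 1.31 in h2b(RNAi), where all kept cells had 0.641, 0.743 and 0.604. In methanol replicate 2 it was 0.911 against 0.580 and in DMSO 0.610 against 0.466. Less apart were gfp(RNAi) (0.765 against 0.617), unfixed replicate 2 (0.676 against 0.609) and day 2 (0.942 against 0.958). Cells of cluster 15 thus stay open as a source. It held 0.961% of cells at day 0 and 1.01% at day 4, so its recovered cells were not a smaller share. Of clusters with at least 20 cells at day 0, cluster 22 fell most, from 1.88% to 0.126%, far less than dd_Smed_v6_100_0 did. X1 also nearly lacked both features, at 26.0 and 92.6 CPM. The highest day 4 to day 0 ratio over 9 clusters was 0.0294. It decides nothing about fewer cells of 1 class at day 4, since the loss of a source of free RNA would lower both features in every cluster. The shares above go against a class recovered as a cluster of at least 20 cells at day 0. A smaller cluster, or a class broken up before capture, stays open. For the other 111 features lower at day 4, the ratio of barcodes with under 200 features to kept cells at day 0 was taken. Its median log2 value lay at the 30.1 percentile of random lists (-0.78 against -0.73), so the list as a whole was not raised in those barcodes. Free RNA stays open for single features, which were not tested. Those barcodes also hold transcripts of cells, as the X1-high shares above show. A difference between the days in the animals stays open and was not tested.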
